A study of Danio rerio with 2 samples.

How the data were processed

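Single-cell RNA-seq was measured with the 10x 3' v3.1 kit in the epidermis of 6-month-old zebrafish whose spic promoter drives EGFP, with 8000 EGFP-positive and 50000 singlet cells sorted from 6 fish and a target of 100000 read pairs per cell, per the labels' protocols. Whether these cell and fish numbers hold for each library or for both together is not given in the sources used here. The deposited matrices hold raw UMI counts per gene and barcode, made with Cell Ranger 4 per the file headers, and were not filtered for cells. The submitters' processing notes name Cell Ranger, Seurat 4.0.5 and the GRCz11 and danRer11 builds, and the annotation version is not given in the sources used here. The files hold 25108 features, of which 1222 share a symbol with another feature and were kept apart by gene ID. They include a DsRedx sequence. The EGFP transcript was not analysed here.

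Replicate 1 had 1536944 barcodes and 51149946 UMIs, and replicate 2 had 1471134 barcodes and 52460166 UMIs. Barcodes with at least 1000 UMIs, at least 300 genes and at most 20% mitochondrial UMIs were kept (4505 and 4750 passed the UMI minimum, and 849 and 927 exceeded the mitochondrial maximum). Scrublet, run per library through scanpy, marked 0.356% and 0.236% of cells, below the minimum of 0.5% set beforehand, so the highest-scoring 0.8% per 1000 cells were removed instead (107 and 117 cells). This left 3545 and 3702 cells holding 80.1% and 79.1% of the UMIs, with a median of 1697 and 1665 genes.

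Both libraries were clustered together on 2000 variable genes, 40 principal components and 15 neighbours with the Leiden algorithm at resolution 1, without batch integration. Clusters were named X-like from marker lists fixed before the data were examined (220 entries in 23 lists, of which 203 matched a symbol and 17 did not). A marker counted at 20 CPM or more and at least 4 times the lower quartile of the clusters, and a name needed 3 markers. Clusters stayed unnamed where few markers were found, where another class scored above 0.9 of the best score, where a marker of another class led, where UMIs were low without a leading marker, or where doublet scores and UMIs were high. That scoring rule was completed after the clusters had been seen. Superficial and basal keratinocyte names were joined into the keratinocyte-like class. Cells were not treated as replicates.

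UMI counts were summed per library and class, and the 14 sums of the 7 classes with at least 20 cells in both libraries entered 1 fit over 11893 genes with 7 residual degrees of freedom. The test was edgeR's quasi-likelihood test with TMM scaling and filterByExpr, with Benjamini-Hochberg adjustment, and genes were called at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. The SE of a log2 fold change was its absolute value divided by the square root of the quasi-likelihood F. It is therefore not a spread measured over the libraries of the classes compared. Levels in CPM are not TMM-scaled, so their ratio can differ from the fitted fold change. The common biological coefficient of variation was 0.108. Where a class had 0 UMIs over both libraries, a bound was computed against a floor of 3 counts over the class, and with 1 to 3 UMIs a ratio with a 95% counting interval, both of which cover counting error only. Gene lists fixed beforehand (549 entries in 19 lists, 512 matched and 37 not) were tested with limma's camera with a preset inter-gene correlation of 0.01, and again with an estimated correlation. Of the preset calls, 1 of 12 held with an estimated correlation against keratinocyte-like cells (MHC class II presentation) and 4 of 11 against macrophage-like cells (lysosome, pattern recognition, myeloid transcription factors and tight junction). Shares of cells with a UMI were compared after thinning each cell to 1000 UMIs, and the shares of classes carry 95% exact binomial intervals per library.

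The genes named were, for both comparisons of metaphocyte-like cells, the 10 with the largest fold change in each direction among called genes with at least 50 CPM in the higher class and the same direction in both libraries, leaving out clone names, mitochondrial and ribosomal genes and markers of the 2 classes. To these were added up to 2 members of each list that rose most and 2 that fell most, and a fixed set with spic, il22ra2, il22, mpeg1.1, cldnh, epcam, cdh1, csf1ra, csf1rb, krt4, krt5 and any reporter sequence. Genes of the keratinocyte-like against macrophage-like comparison, of the other classes and of the closing observations were chosen after their values were seen.

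The 2 libraries were compared before averaging: in metaphocyte-like, keratinocyte-like and macrophage-like cells, 27, 9 and 66 of 100 random divisions of the cells differed at least as much as the libraries did. They shared 3 barcodes of at least 1000 UMIs where chance gives 3.15, so they did not hold the same cells and were counted as 2 samples. That result would also arise with 2 loadings of a single pool of cells. The random divisions showed no spread between libraries clearly beyond the sampling of cells, so p-values may measure little more than that sampling. Barcodes of at least 1000 UMIs in replicate 1 were found among those of 10 to 100 UMIs in replicate 2 in 2639 cases where chance gives 60.0, so part of the UMIs outside cells belonged to cells of the other library, and the subtraction of RNA from such barcodes was repeated with barcodes found in 1 library only. All class sums of a replicate come from the same library, which pairs them by design, and over 21 pairs of classes the correlation of deviations from the class means had a median of 0.0244 and a range of -0.142 to 0.156 (genes of at least 50 CPM).

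The test was tested on simulated data with known changes, and recovery was counted by the adjusted p without the fold minimum. For metaphocyte-like against keratinocyte-like cells, 61 of 70 genes changed 2-fold (87.1%) and 82 of 84 changed 4-fold (97.6%) were recovered, over 8385 genes. Only changed genes that passed the count filter are counted. Apart from the changed genes, all simulated classes shared an average profile and a common dispersion. The simulation therefore did not cover scaling or spread per gene as in these data. Alternatives fixed beforehand were DESeq2 with its size factors, no filter on low counts, only the 2 classes compared in the fit, a replicate block, each library left out, UMI minimums of 500 and 2000, a mitochondrial maximum of 10%, doublet calls kept, clustering resolutions of 0.5 and 2, clustering without list and marker genes, subtraction of RNA measured in barcodes of 10 to 100 UMIs, separate random parts of the UMIs for clustering and test, and an estimated correlation. Subtraction with barcodes of 1 library, and a mitochondrial maximum of 10% for the gene lists, were added after the data were seen. The tools were Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.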

Results

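The 2 libraries held single-cell transcriptomes of the epidermis of 6-month-old zebrafish that carry an EGFP reporter under the promoter of spic, a gene for an ETS-family transcription factor. EGFP-positive cells were sorted together with singlet cells taken without regard to the reporter, so that the libraries were enriched for metaphocytes, which are myeloid-like cells of ectodermal origin found in fish barrier tissues. Both libraries carried the same labels and formed a single group of 2 samples. Replicate 1 held 51149946 UMIs and gave 3545 kept cells with a median of 7498 UMIs, and replicate 2 held 52460166 UMIs and gave 3702 kept cells with a median of 7336. The comparisons were made between cell classes inside these libraries, with the library as the replicate (n = 2 throughout, values as mean ± SD unless a log2 fold change ± SE is given). No label used here says that the libraries came from separate fish, so all p-values measured the spread between libraries only, which may be technical.

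Keratinocyte-like cells made up 51.1% ± 0.0629 of the kept cells (3703 cells, SD, n = 2), T or NK cell-like cells 13.3% ± 0.00268 and metaphocyte-like cells 11.6% ± 0.123 (844 cells). Merkel or neuroendocrine-like cells, which carried atoh1a and insm1a, made up 6.31% ± 0.509, fibroblast-like cells 4.99% ± 0.472, mucous or goblet-like cells with muc5.1 and agr2 2.58% ± 0.214 and macrophage-like cells 2.55% ± 0.429 (184 cells). B cell-like and neutrophil-like cells were the rarest classes, with 40 and 35 cells. Clusters that stayed without a name held 6.51% ± 0.492 of the cells. Among them, cluster 14 (3.19% and 2.73% of the 2 libraries) was led by gata2b and avil and carried the chemosensory-cell regulator pou2f3 at 909.7 ± 52.2 CPM. That gene stood at 235 ± 13.9, 242 ± 4.12 and 369 ± 0.442 CPM in the metaphocyte-like clusters, 391 ± 61.7 CPM in the mucous or goblet-like cluster and 295 ± 5.21 CPM in the keratinocyte-like cluster 21. The unnamed cluster 20 held more of it than these, at the level given under the other observations. Cluster 13 (1.44% and 1.16%) carried the T cell genes cd4-1 at 544 ± 106 CPM and il21 at 2005 ± 1228 CPM, with cd8a among its markers too. It stayed unnamed because its median of 2234 UMIs was low and no marker was among its top 10 genes. Its T or NK cell score of 4.70 (11 markers) was above those of the named clusters 5, 11 and 17 (2.68, 4.12 and 4.14). Clusters 5 and 11 had medians of 2648.5 and 2799.5 UMIs. The T or NK cell-like share thus leaves out a cluster with a higher score. Cluster 16 (0.564% and 0.513%) held macrophage and dendritic cell markers alike, with ccl35.1 at 63503 ± 4080.0 CPM and the cytokine gene tnfa at 1082 ± 525 CPM. Cluster 20 (0.536% and 0.837%) was led by the retinoic acid synthesis gene aldh1a3, and cluster 22 (1.13% and 0.918%) shared leading genes with cluster 14, held superficial keratinocyte markers and had high doublet scores and UMI counts. The libraries mixed sorted EGFP-positive cells with singlet cells, so none of these shares estimates the makeup of the skin. How much of the metaphocyte-like share came from the EGFP-positive sort cannot be told here. The rule that keeps clusters unnamed was completed after the clusters had been seen. The T or NK cell-like share was 0.488% with a mitochondrial maximum of 10%, 1.46% with a minimum of 2000 UMIs and 8.25% with doublet calls kept. The Merkel or neuroendocrine-like share was 1.202% with a minimum of 2000 UMIs and 9.10% with a minimum of 500. With separate parts of the UMIs no cluster took that name. Clusters without a name held 21.0% of the cells with the mitochondrial maximum of 10%, 16.6% with 2000 UMIs, 14.8% with doublet calls kept and 11.5% with separate parts, and B cell-like cells kept their name in 2 of the alternatives only.

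**Figure D1:**
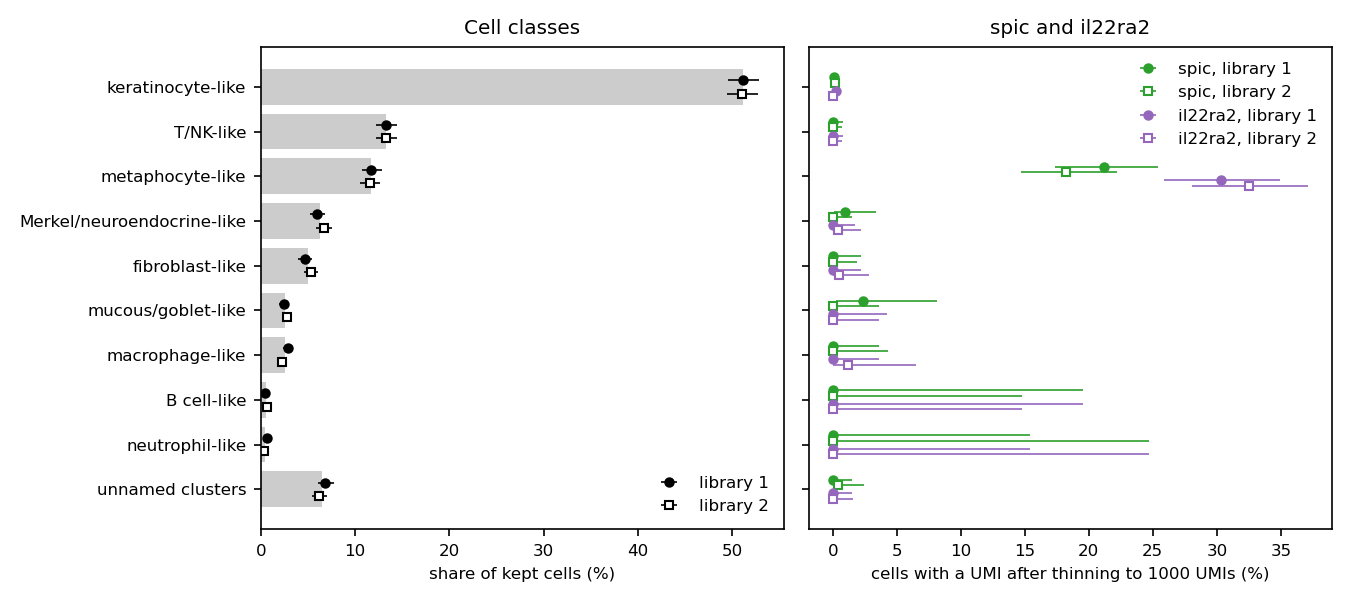
Share of kept cells in each class (left, percent; bars show the mean of the 2 libraries, symbols each library with its 95% exact binomial interval) and share of cells with at least 1 UMI of spic or il22ra2 after thinning each cell to 1000 UMIs (right, percent; symbols as on the left). Metaphocyte-like cells lie at 19.7% for spic and 31.4% for il22ra2, and keratinocyte-like cells near 0.

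The level of spic and of the IL-22 signalling genes was compared across classes because spic drives the reporter of the sort and because il22ra2 encodes a secreted IL-22-binding protein. Both genes served as markers for naming the metaphocyte-like class, so their levels describe that class and are not independent results. spic stood at 233 ± 4.53 CPM in metaphocyte-like cells and at 1.84 ± 0.461 CPM in keratinocyte-like cells, a log2 fold change of 6.58 ± 0.23. il22ra2 stood at 451 ± 23.7 and 1.29 ± 0.315 CPM, a log2 fold change of 8.03 ± 0.21. After thinning to 1000 UMIs, spic was seen in 19.7% ± 2.07 of metaphocyte-like and 0.107% ± 0.0732 of keratinocyte-like cells. Unthinned, these shares were 85.0% ± 1.54 at a median of 15246 UMIs and 1.25% ± 0.266 at a median of 12168. For il22ra2, the thinned shares were 31.4% ± 1.55 and 0.164% ± 0.158, and the unthinned shares 74.0% ± 2.16 and 1.16% ± 0.00404. In the mucous or goblet-like class spic reached 34.3 ± 21.1 CPM (62 UMIs), a log2 fold change of 3.45 ± 0.40 against keratinocyte-like cells (adjusted p = 1.9e-06 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), while il22ra2 had 1 UMI there. These spic UMIs all lay in 14 of the 187 cells of the class. The cytokine gene il22 itself had 5 UMIs in T or NK cell-like cells, 1 in fibroblast-like cells and 0 in all other classes, which was too few for a test. stat3, the transcription factor downstream of the IL-22 receptor, stood at 56.8 ± 2.38 CPM in metaphocyte-like and 18.6 ± 0.988 CPM in keratinocyte-like cells (log2 fold change 1.22 ± 0.11). Its level was 70.7 ± 4.34 CPM in mucous or goblet-like cells (1.18 ± 0.15 against keratinocyte-like cells), 56.2 ± 4.64 CPM in T or NK cell-like cells (0.97 ± 0.13) and 47.1 ± 2.83 CPM in macrophage-like cells (0.89 ± 0.18). Merkel or neuroendocrine-like cells held 205 ± 7.02 CPM of stat3 and 1424 ± 287 CPM of socs3b, a feedback inhibitor of the pathway, with log2 fold changes of 2.17 ± 0.15 and 7.34 ± 0.18 against keratinocyte-like cells. In fibroblast-like cells socs3b stood at 165 ± 6.27 CPM (5.32 ± 0.17), and socs3a differed from keratinocyte-like cells by 3.18 ± 0.15 in fibroblast-like, 3.67 ± 0.16 in Merkel or neuroendocrine-like and -0.57 ± 0.14 in metaphocyte-like cells. The adjusted p was at most 4.8e-06 for the stat3, socs3b and socs3a differences given here that reached the fold minimum (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The shared receptor subunit gene crfb4 stood at 55.7 ± 0.372 against 27.6 ± 0.191 CPM, and its fitted log2 fold change of 0.63 ± 0.12, which includes TMM scaling, lay under the minimum of 1. The Merkel or neuroendocrine-like cells had a median of only 1376 UMIs, and the receptor gene il22ra1 and the EGFP transcript were not analysed here.

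**Figure D2:**
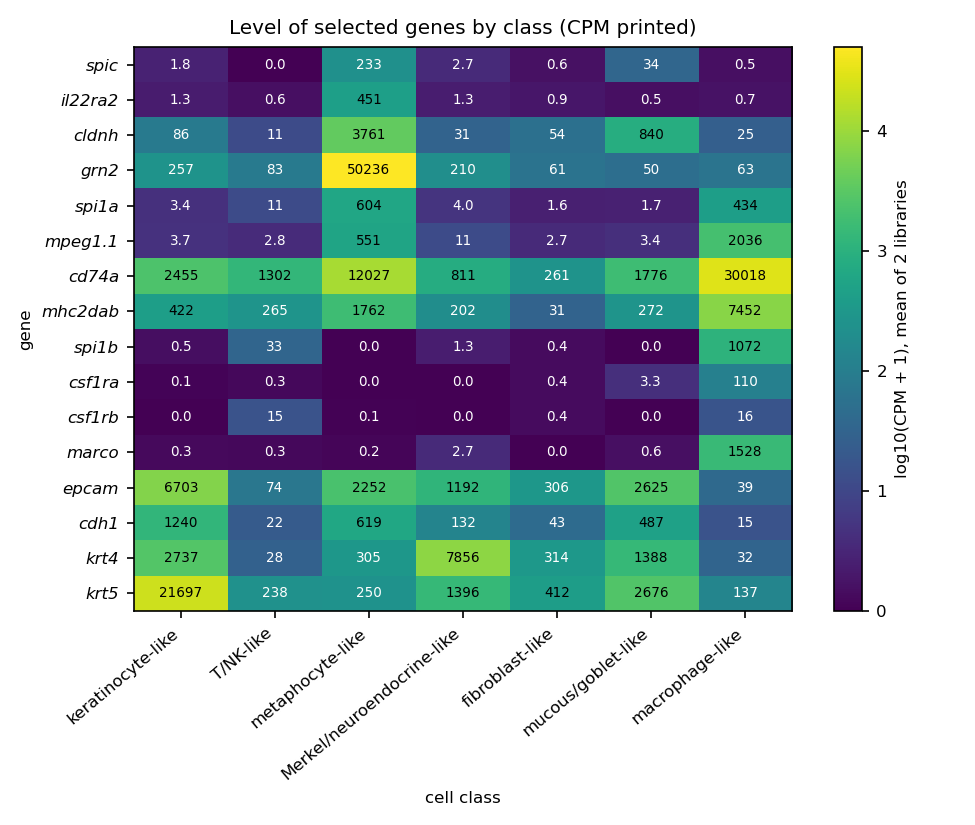
Level of 16 selected genes (vertical axis) in the 7 classes that entered the fit (horizontal axis), with log10 of the mean CPM of the 2 libraries plus 1 as colour and that mean CPM as the printed number. Metaphocyte-like cells share spi1a and mpeg1.1 with macrophage-like cells and epcam and cdh1 with keratinocyte-like cells, with 0 UMIs of csf1ra and spi1b.

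Metaphocyte-like cells differed from keratinocyte-like cells in 5323 of 11893 genes, 2436 higher and 2887 lower. il12bb, a subunit gene of the IL-12 cytokine family, stood at 758 ± 49.5 CPM against 1.94 ± 1.13 CPM (log2 fold change 8.20 ± 0.31), the granulin gene grn1 at 3971 ± 43.4 against 12.5 ± 5.08 CPM (7.92 ± 0.28) and the chemokine gene ccl35.1 at 2666 ± 139 against 10.8 ± 1.79 CPM (7.56 ± 0.50). The cadherin gene cdh28 (7.75 ± 0.19), the opsin gene opn1sw2 (7.43 ± 0.20), the Toll-like receptor gene tlr4al (7.43 ± 0.23), the cytokine receptor gene crfb15 (7.41 ± 0.24), ly86, whose product partners a Toll-related receptor (7.28 ± 0.21), the adaptor gene dok2 (7.27 ± 0.20) and the lysophospholipid receptor gene gpr34b (7.25 ± 0.22) followed. The cytochrome P450 genes cyp8b3 (-8.75 ± 0.31) and cyp8b2 (-8.35 ± 0.32), the sterol synthesis gene hsd17b7 (-8.25 ± 0.44), the organic solute transporter gene slc51a (-8.43 ± 0.23), the ammonium transporter gene rhcgl1 (-8.02 ± 0.32), apnl (-8.21 ± 0.29) and dhrs13a.2 (-7.93 ± 0.26) were lower, as was the complement factor D gene cfd at 13.5 ± 0.0883 against 2933 ± 54.4 CPM (-8.15 ± 0.26). The glypican gene gpc1a had 1 UMI in metaphocyte-like cells, a ratio of 639.8 (counting interval 115 to 25269.5), and the epithelial small GTPase gene rab25a had 2 UMIs, a ratio of 323 (counting interval 89.4 to 2666). The epithelial adhesion gene epcam was lower at 2252 ± 12.9 against 6703 ± 271 CPM (-1.96 ± 0.22) and the E-cadherin gene cdh1 at 619 ± 32.4 against 1240.4 ± 18.9 CPM (-1.39 ± 0.16). The adjusted p was at most 6.0e-07 for each of these genes (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and 5314 of the called genes went the same way in both libraries. With doublet calls kept, the split of called genes turned to 2774 higher and 2486 lower, and with a mitochondrial maximum of 10% to 2768 higher and 2340 lower. The classes were built from the counts that were tested. In an alternative, the UMIs of each cell were split at random so that clustering and test used separate parts. There, 4294 of 9427 tested genes were called, on fewer UMIs. Of the 4410 genes called with all UMIs and tested there, 4166 were called again in the same direction.

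Gene lists written down beforehand were tested between metaphocyte-like and keratinocyte-like cells. Of the MHC class II presentation genes, 11 of 14 measured members rose and 0 fell, with the activation marker gene cd83 at 271 ± 12.7 against 4.27 ± 0.121 CPM (5.59 ± 0.18) and the cathepsin S gene ctss2.2 at 3.74 ± 0.18. This was the only list called both ways, at adjusted p = 1.9e-05 in limma's camera test with a preset correlation and adjusted p = 0.034 with an estimated correlation. Of the phagocytosis and scavenger genes, 15 of 25 measured members rose and 3 fell (camera adjusted p = 1.9e-05; adjusted p = 0.11 with an estimated correlation), including the integrin genes itgb2 (7.22 ± 0.18) and itgam (6.61 ± 0.31). Among its members that fell, gulp1a had 0 UMIs in metaphocyte-like cells and was at least 3.37-fold lower, and c1qb at least 1.39-fold lower at only 0.346 ± 0.123 CPM in keratinocyte-like cells. The c1qb call was lost after subtraction of the RNA measured in empty barcodes and with clustering and test on separate parts of the UMIs. Of the lysosome genes, 19 of 35 measured members rose and 2 fell (camera adjusted p = 0.0017; adjusted p = 0.11 with an estimated correlation). Examples were laptm5 at 6.76 ± 0.21 and the cathepsin L gene ctsla at -3.38 ± 0.18, scarb2a at -3.03 ± 0.20. In the IL-22 axis list, 5 of 8 measured members rose and 0 fell (camera adjusted p = 0.0029; adjusted p = 0.065 with an estimated correlation); without il22ra2, which named the class, 4 rose, socs3b among them (2.84 ± 0.17). In the pattern recognition and inflammation list, 12 of 22 measured members rose and 6 fell (camera adjusted p = 0.042; adjusted p = 0.11 with an estimated correlation; adjusted p = 0.054 with the replicate block). Its adjusted p was 0.08 with clustering and test on separate parts of the UMIs and 0.082 with a mitochondrial maximum of 10%. Its Toll-like receptor genes tlr1 (7.68 ± 0.32) and tlr8b (6.95 ± 0.42) rose, while the neutrophil-attracting chemokine genes cxcl8a (-5.06 ± 0.43) and cxcl8b.1 (-6.35 ± 0.82) fell.

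Keratin and junction gene lists were tested in the same way. Of the keratins, 2 of 16 measured members rose and 13 fell (camera adjusted p = 3.8e-05; adjusted p = 0.065 with an estimated correlation). Examples were krt15 at -7.85 ± 0.36 and krt97 at -7.84 ± 0.28, and 7 of those that fell were not used to name the keratinocyte-like class. The simple-epithelium keratins krt18b at 1851 ± 68.7 against 12.7 ± 1.06 CPM (6.80 ± 0.67) and krt8 (1.61 ± 0.31) were the members that rose. Of the adherens junction, desmosome and epithelial identity genes, 1 of 33 measured members rose and 27 fell (camera adjusted p = 5.1e-09; adjusted p = 0.065 with an estimated correlation). The epithelial transcription factor gene grhl2b rose (2.69 ± 0.17), whereas its relative grhl1 had 1 UMI in metaphocyte-like cells, a ratio of 123 (counting interval 22.1 to 4858), and the desmosomal gene pkp1a was at least 9.74-fold lower. Of the tight junction genes, 2 of 27 measured members rose and 15 fell (camera adjusted p = 0.0043; adjusted p = 0.065 with an estimated correlation). Examples were cldn1 at -7.46 ± 0.26, cgnl1 at least 55.9-fold lower and tjp2b higher (1.78 ± 0.12). The lipid and cholesterol list held 2 genes that rose and 11 that fell of 20 (camera adjusted p = 0.0073; adjusted p = 0.065 with an estimated correlation). Examples were the sterol synthesis gene hmgcra at -6.87 ± 0.23 and the apolipoprotein gene apoeb at -6.77 ± 0.52. Of the interferon response genes, 1 of 27 measured members rose and 11 fell (camera adjusted p = 0.031; adjusted p = 0.11 with an estimated correlation). Examples were rsad2 at -4.82 ± 0.25 and ifit8 at -4.70 ± 0.36; irf7, at 1.00 ± 0.13, lay at the fold minimum and fell below it in 5 of the alternatives. Of the cell cycle genes, 0 of 27 measured members rose and 13 fell, with mcm3 at -4.09 ± 0.40 and mcm5 at -4.44 ± 0.53 (camera adjusted p = 0.042; adjusted p = 0.54 with an estimated correlation and 0.72 at clustering resolution 2). The cell cycle call was also lost without list and marker genes in the clustering (adjusted p = 0.062), with separate parts of the UMIs (0.062) and with a mitochondrial maximum of 10% (0.59), all in camera. Under that maximum the direction turned, as 9 of 29 members rose and 7 fell, and the median log2 fold change went from -1.05 to 0.78. Of the dissociation stress genes, 1 of 30 measured members rose and 25 fell (camera adjusted p = 3.7e-07; adjusted p = 0.16 with an estimated correlation). Examples were the immediate early genes egr2a (-5.63 ± 0.20) and fosl1a (-5.57 ± 0.21) lower and klf6a higher (1.06 ± 0.16). Beside this, 2 keratinocyte-like clusters with 813 cells had median mitochondrial shares of 10.7% or more, against 3.12% to 3.23% in the metaphocyte-like clusters. With a maximum of 10%, an alternative chosen for the lists after the data were seen, the counts of stress genes were again 1 and 25.

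The other lists had members on both sides and passed no list test. Of the myeloid transcription factors, 8 of 24 measured members rose and 10 fell (camera adjusted p = 0.87). Examples were spi1a, a PU.1 gene, at 604 ± 27.7 against 3.43 ± 0.202 CPM (7.06 ± 0.31), ikzf1 at 6.18 ± 0.24, and the C/EBP genes cebpd and cebpa at -6.55 ± 0.33 and -6.18 ± 0.27. Of the chemokine and migration genes, 5 of 19 measured members rose and 8 fell (camera adjusted p = 0.66); the log2 fold change was 7.05 ± 0.26 for the chemokine gene ccl20a.3 and 6.46 ± 0.25 for the chemokine receptor gene ccr9a, whereas cxcl14 had 3 UMIs, a keratinocyte to metaphocyte ratio of 159 (counting interval 54.3 to 769.6). The iron and heme list held 5 genes that rose and 9 that fell of 21 (camera adjusted p = 0.51). Examples were the ferritin gene fth1a at 7583 ± 75.5 against 692 ± 10.8 CPM (3.07 ± 0.14). The hemidesmosome and basement membrane list had 4 and 8 of 16 (camera adjusted p = 0.25). Examples were itga3a at 3.51 ± 0.18 and fermt1 at least 33.5-fold lower. The antimicrobial list had 3 and 7 of 14 (camera adjusted p = 0.55). Examples were bpifcl at 6.40 ± 0.31 and nos2a at -6.16 ± 0.36. The endocytic uptake list had 5 and 4 of 19 (camera adjusted p = 0.25). Examples were the caveolin gene cav1 at -7.30 ± 0.38 and rab11ba at 2.13 ± 0.13; its median log2 fold change was 0.26 and its mean -0.32. The T and NK cell list had 3 and 2 of 10 (camera adjusted p = 0.21). Examples were the costimulatory receptor gene cd28 at 4.67 ± 0.26. Adjusted over the list alone, 3 lipid genes rose and every other count given here for the 19 lists was as over all genes. Without the genes that had named a class, 1 and 13 tight junction genes rose and fell, 1 and 24 of the adherens and desmosome list, 4 and 5 of the hemidesmosome list, 8 and 9 of the myeloid transcription factors and 3 and 6 of the antimicrobial list. The median log2 fold change was -1.69 for the chemokine list and -0.87 for the myeloid transcription factors, and 0.00 and -0.22 with genes at 0 UMIs set to their bound. With a mitochondrial maximum of 10% the median of the myeloid transcription factors was 0.29.

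The remaining genes of the rule showed further differences from keratinocyte-like cells. Of the genes that had named a class, the claudin gene cldnh stood at 3761 ± 137 against 85.8 ± 3.38 CPM (log2 fold change 5.07 ± 0.37) and mpeg1.1 at 551 ± 8.48 against 3.74 ± 0.533 CPM (6.81 ± 0.26), whereas krt4 (-3.55 ± 0.20) and krt5 (-6.82 ± 0.23) were lower. The CSF-1 receptor genes csf1ra and csf1rb had 0 and 1 UMIs in metaphocyte-like cells and 5 and 2 in keratinocyte-like cells, which gave no call. Among list members, the sorting nexin gene snx5 (1.97 ± 0.13), the basement membrane gene fras1 (2.74 ± 0.28), the peptidoglycan recognition gene pglyrp5 (3.03 ± 0.20), the transferrin receptor gene tfr1b (3.06 ± 0.17), the desaturase gene scdb (3.79 ± 0.74) and the lipase gene lipea (1.29 ± 0.25) were higher. The lipoprotein receptor gene lrp1ab (-6.45 ± 0.25) was lower, as was the integrin gene itga6b (-7.50 ± 0.24), which had also named the keratinocyte-like class. The chemokine gene ccl20b had 2 UMIs in metaphocyte-like cells, a ratio of 152 (counting interval 42.0 to 1252), and the ferritin-like gene fthl31 (ENSDARG00000094210) was at least 10.9-fold lower. The adjusted p was at most 2.2e-04 for each called gene so far in this group (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The metalloreductase gene steap4, with 0 UMIs against 0.275 ± 0.134 CPM in keratinocyte-like cells, lost its call with clustering and test on separate parts of the UMIs, the T cell kinase gene lck, at 2 UMIs and a ratio of 3.73 (counting interval 1.03 to 30.8), under the same split, with DESeq2 and at resolution 0.5, and the adaptor gene sla2 (-1.49 ± 0.38) with doublet calls kept.

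**Figure D3:**
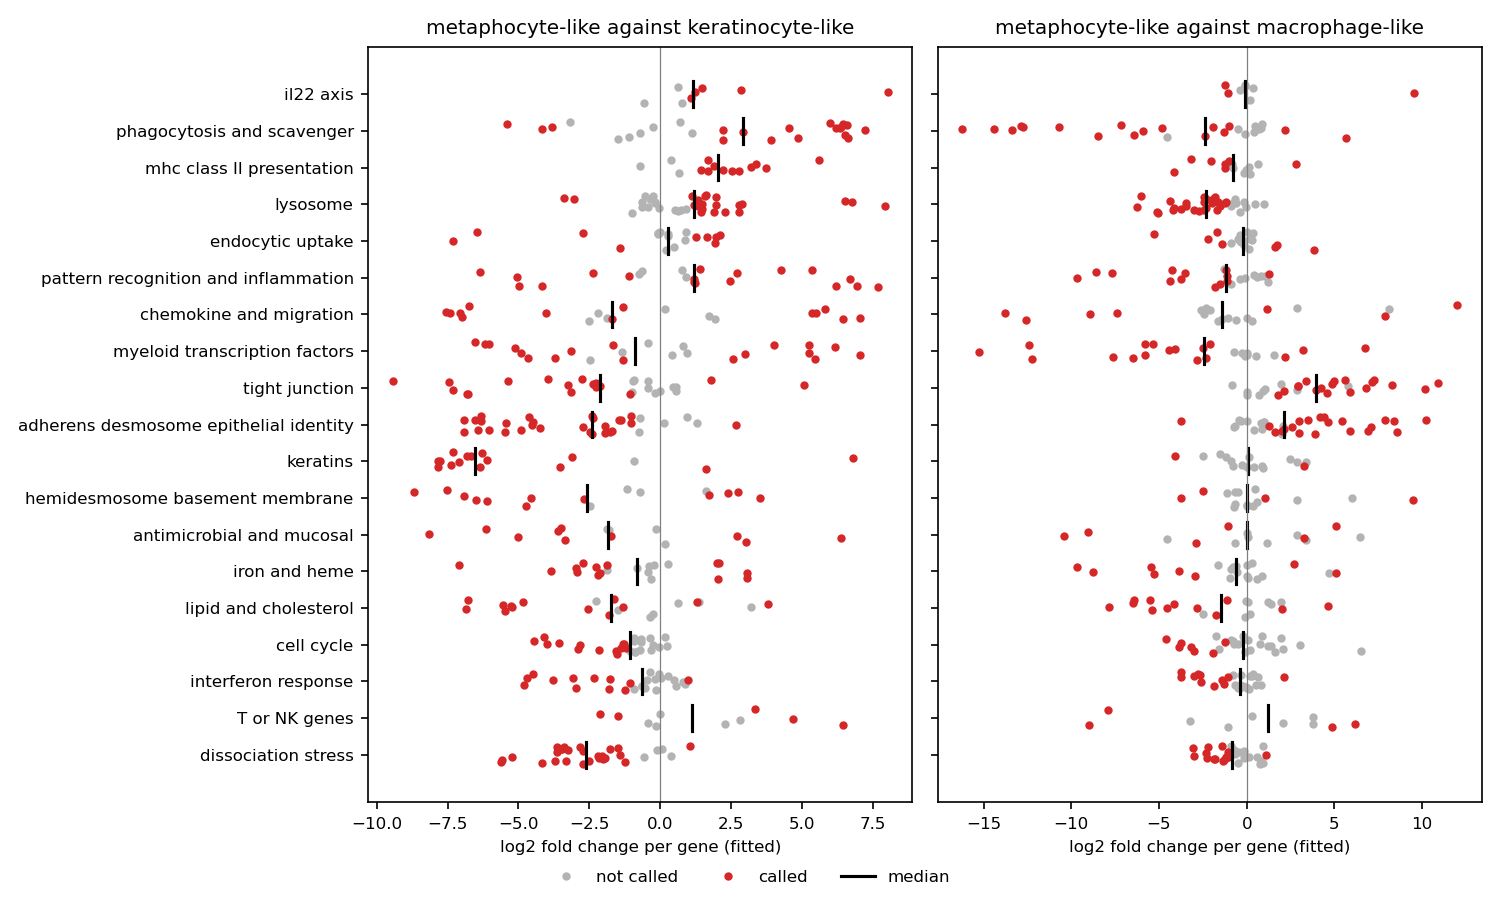
Fitted log2 fold change (horizontal axis) of each measured member of the 19 fixed lists (vertical axis) for metaphocyte-like against keratinocyte-like cells (left) and against macrophage-like cells (right), with genes as points (red where called, grey where not), list medians as bars and, for genes with 0 UMIs in a class, fitted values that are not bounds. Tight junction genes lie mostly below 0 on the left, where 15 of 27 fell, and above 0 on the right, where 18 rose.

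Metaphocyte-like cells were set against macrophage-like cells as the immune reference, chosen beforehand because metaphocytes resemble tissue macrophages. The 2 classes differed in 3874 genes, 1957 higher and 1917 lower in metaphocyte-like cells. Epithelial genes stood among those higher, with epcam at 2252 ± 12.9 against 38.8 ± 1.31 CPM (log2 fold change 5.91 ± 0.30) and cdh1 at 619 ± 32.4 against 15.1 ± 1.47 CPM (5.40 ± 0.25). Macrophage regulators were among the genes that were lower. spi1b, the other PU.1 gene, had 0 UMIs in metaphocyte-like cells and was at least 4337-fold lower than the 1072 ± 107 CPM of macrophage-like cells, and the CSF-1 receptor gene csf1ra at least 449-fold lower. Its paralog csf1rb had 1 UMI, a ratio of 190.3 (counting interval 34.1 to 7515), and the macrophage transcription factor gene mafbb 3 UMIs, a ratio of 6359 (counting interval 2176 to 30836). csf1ra and spi1b were on the macrophage marker list, and spi1b on that for metaphocytes too. Genes with 0 UMIs in macrophage-like cells were headed by nipal4, a magnesium transporter family gene, at 392 ± 4.86 CPM and at least 215-fold higher, nme2b.2 (at least 154-fold), mctp2b (at least 139-fold), the protease inhibitor gene spink4 (at least 109-fold), lrmp (at least 92.5-fold) and grtp1b (at least 88.4-fold). The connexin gene cx30.9 was at least 68.3-fold higher, gpr34b at least 64.0-fold and tlr4al at least 56.6-fold. The chemokine gene ccl19a.1 was at least 59.4-fold higher, but its 108 ± 75.4 CPM differed widely between the libraries. In the other direction, 2 MFAP4 copies (ENSDARG00000089667 and ENSDARG00000088745), whose reads may be shared between copies, had 0 UMIs in metaphocyte-like cells and were at least 3027-fold and 1042-fold lower. The urokinase gene plaua was at least 2508-fold lower, the chemokine gene ccl34b.8 2029-fold, the versican gene vcanb 1798-fold, rgl1 1288-fold, the mannose receptor gene mrc1b 1173-fold, the chemerin receptor gene cmklr1 1103-fold and cx32.2 805-fold. tppp had 3 UMIs in metaphocyte-like cells and 3282 ± 578 CPM in macrophage-like cells, a ratio of 12940.1 (counting interval 4428 to 62748). mpeg1.1, a marker of both classes, was lower at 551 ± 8.48 against 2036 ± 293 CPM (-1.83 ± 0.20), and the 0.93 ± 0.20 of krt5 did not reach the fold minimum, although it did in 7 of the alternatives. The adjusted p was at most 4.7e-05 for each called gene named here (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The macrophage-like class had only 184 cells. Among changed genes that passed the count filter, the simulated test of this comparison recovered 22 of 70 changed 2-fold (31.4%) and 64 of 84 changed 4-fold (76.2%), over 8385 genes. The median log2 fold change of all genes was 0.15 in edgeR and 0.00 with DESeq2's size factors, with a median difference per gene of -0.16, so genes near the fold minimum depend on the scaling. With DESeq2, called genes numbered 1526 higher and 2181 lower.

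Among the fixed lists, the lysosome genes had the lowest adjusted p against macrophage-like cells in camera with a preset correlation. Of 35 measured members, 0 rose and 26 fell, including the cathepsin genes ctsd at 39.8 ± 1.26 against 3131 ± 144 CPM (-6.24 ± 0.18) and ctsla (-6.02 ± 0.20). The list passed camera at adjusted p = 4.0e-19, and at adjusted p = 0.007 with an estimated correlation. Of the tight junction genes, 18 of 27 measured members rose and 0 fell (camera adjusted p = 8.2e-08; adjusted p = 0.014 with an estimated correlation). Examples were cldn23b at least 28.0-fold and marveld2b at least 16.8-fold higher; adjusted over the list alone 19 rose. Of the adherens junction, desmosome and epithelial identity genes, 20 of 33 measured members rose and 1 fell (camera adjusted p = 1.1e-06; adjusted p = 0.078 with an estimated correlation). Examples were grhl2b at least 17.3-fold and the polarity gene crb3a at least 5.56-fold higher. Of the myeloid transcription factors, 3 of 24 measured members rose and 14 fell (camera adjusted p = 8.2e-08; adjusted p = 0.007 with an estimated correlation), and adjusted over the list alone 4 rose. batf3, a dendritic cell factor, was higher (3.19 ± 0.40), and zeb2b, with 0 UMIs in macrophage-like cells, was at least 1.55-fold higher at adjusted p = 0.046 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and 0.071 with the replicate block. Of the pattern recognition and inflammation genes, 1 of 22 measured members rose and 12 fell (camera adjusted p = 8.9e-05; adjusted p = 0.014 with an estimated correlation). Examples were cxcl8a at 8.70 ± 4.73 against 3521 ± 760.0 CPM (-8.59 ± 0.48) and the flagellin receptor gene tlr5b at least 92.7-fold lower. Of the phagocytosis and scavenger genes, 2 of 25 measured members rose and 15 fell (camera adjusted p = 1.1e-07; adjusted p = 0.06 with an estimated correlation), 10 of the latter outside the macrophage markers. The complement genes c1qb and c1qa, both macrophage markers, were at least 8296-fold and 2356-fold lower, whereas itgam had 1 UMI in macrophage-like cells, a ratio of 50.3 (counting interval 9.03 to 1986). Of the MHC class II presentation genes, 1 of 14 measured members rose and 6 fell (camera adjusted p = 0.0074; adjusted p = 0.06 with an estimated correlation); outside the macrophage markers only lgmn fell (-4.15 ± 0.17), and the class II transactivator gene ciita rose (2.78 ± 0.33). The iron and heme list (2 of 21 measured members rose and 6 fell; camera adjusted p = 0.0074; adjusted p = 0.054 with an estimated correlation) included the transferrin receptor gene tfr1b, with 2 UMIs in macrophage-like cells and a ratio of 32.9 (counting interval 9.12 to 272), and the ferritin-like gene fthl28 (-9.68 ± 0.33). In the lipid and cholesterol list 2 of 20 measured members rose and 10 fell (camera adjusted p = 0.018; adjusted p = 0.06 with an estimated correlation and 0.081 with clustering and test on separate parts of the UMIs). Examples were the fatty acid synthase gene fasn at 1.99 ± 0.28 and the cholesterol exporter gene abca1b at -7.83 ± 0.36. In the interferon response list 1 of 27 measured members rose and 10 fell (camera adjusted p = 0.021; adjusted p = 0.083 with an estimated correlation and 0.065 with a mitochondrial maximum of 10%). Examples were irf7 at 2.13 ± 0.18 and stat1b at -3.73 ± 0.21. In the dissociation stress list 1 of 30 measured members rose and 14 fell (camera adjusted p = 0.0099; adjusted p = 0.56 with an estimated correlation), but with a mitochondrial maximum of 10%, chosen for this list after the data were seen, 2 rose and 8 fell and the adjusted p was 0.17. The median mitochondrial share was 4.53% in macrophage-like cells.

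The remaining lists were not called by camera against macrophage-like cells, except the T and NK cell list with a mitochondrial maximum of 10%. The IL-22 axis list had 1 gene higher and 2 lower of 8 (camera adjusted p = 0.93); the feedback inhibitor genes socs3a (-1.05 ± 0.15) and socs3b (-1.22 ± 0.19) fell and both calls were lost with a mitochondrial maximum of 10%. The chemokine list had 3 and 4 of 19 (camera adjusted p = 0.43). Examples were ccl20a.3 at a log2 fold change of 7.89 ± 0.34. The keratins had 1 and 1 of 16 (camera adjusted p = 0.91). Examples were krt4 at 3.26 ± 0.24 and krt18a.1 at -4.10 ± 0.37. The endocytic list had 3 and 4 of 19 (camera adjusted p = 0.35). Examples were the recycling gene ehd1b at 3.81 ± 0.24 and the lipoprotein receptor gene lrp1ab at -5.30 ± 0.39. The cell cycle list had 0 and 7 of 27 (camera adjusted p = 0.5). Examples were mcm2 at -4.60 ± 0.68, a call lost when doublet calls were kept. The hemidesmosome list had 2 and 2 of 16 (camera adjusted p = 0.93). Examples were plecb at -2.51 ± 0.19 and fras1 at least 10.1-fold higher. The antimicrobial list had 2 and 4 of 14 (camera adjusted p = 0.29). Examples were bpifcl at 3.26 ± 0.43 and the itaconate synthesis gene acod1, at 1 UMI in metaphocyte-like cells, in a ratio of 1895 (counting interval 340.2 to 74859.6). The T and NK cell list had 2 and 2 of 10 (camera adjusted p = 0.58, and 0.048 with a mitochondrial maximum of 10%). Examples were cd4-1 at -9.01 ± 0.41 and cd8a at -7.90 ± 0.34, since the macrophage-like cells carried both. Adjusted over the list alone, the counts of the lists without a count of their own above were as over all genes. Without the genes that had named a class, 17 and 0 tight junction genes rose and fell, 3 and 13 of the myeloid transcription factors, 3 and 3 of the chemokine list and 0 and 2 of the IL-22 axis list. With genes at 0 UMIs set to their bound, the median log2 fold change went from 3.93 to 2.91 for tight junction genes, from 1.19 to 0.00 for the T and NK cell list, from -2.38 to -1.94 for phagocytosis genes and from 2.12 to 2.02 for the adherens and desmosome list. Median and mean log2 fold change differed in sign for the IL-22 axis list (-0.10 and 0.90), the T and NK cell list (1.19 and -0.02) and the antimicrobial list (0.04 and -0.46). The hemidesmosome list had a mean of 0.68 but a downward direction in camera. The median turned in sign with DESeq2 for the T and NK cell list (-0.53), the antimicrobial list (-0.36) and the keratins (0.06 and -0.23), and with a mitochondrial maximum of 10% for the T and NK cell list (-2.66), the IL-22 axis list (0.10) and the endocytic list (-0.22 and 0.03). With clustering and test on separate parts of the UMIs it was -0.13 for the keratins and -0.39 for the hemidesmosome list, whose median was 0.00, and -0.27 with DESeq2. With the mitochondrial maximum of 10%, 3 MHC class II genes fell, and 4 keratins and 3 cell cycle genes rose.

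The remaining genes of the rule showed further differences from macrophage-like cells. The metaphocyte markers cldnh (log2 fold change 7.23 ± 0.46), spic (1 UMI in macrophage-like cells, a ratio of 382 (counting interval 68.6 to 15097)) and il22ra2 (1 UMI, a ratio of 740.4 (counting interval 133 to 29244)) were higher. Among list members, the dynamin gene dnm2a (1.70 ± 0.29) was higher, and agr1 (2 UMIs in macrophage-like cells, a ratio of 33.8 (counting interval 9.36 to 279)), the heme exporter gene flvcr1 (2 UMIs, a ratio of 6.42 (counting interval 1.78 to 53.0)), the fatty acid elongase gene elovl6 (2 UMIs, a ratio of 24.6 (counting interval 6.81 to 203)), tox (1 UMI, a ratio of 73.4 (counting interval 13.2 to 2899)) and cd28 (1 UMI, a ratio of 29.1 (counting interval 5.22 to 1149.7)) were higher too. The macrophage marker ctss2.1 (-3.20 ± 0.16), the early endosome gene rab5b (-2.22 ± 0.19), the desmosomal gene pkp3b (-3.77 ± 0.60), the integrin gene itgb1a (-3.75 ± 0.72), rsad2 (-3.77 ± 0.41) and the heat shock genes hsp90aa1.2 (-3.07 ± 0.52) and hsp70.1 (-3.01 ± 0.43) were lower. The chemokine gene ccl34b.1, also a macrophage marker, was at least 1564-fold and fthl31 (ENSDARG00000094210) at least 48.8-fold lower. The chemokine gene ccl34a.4 had 1 UMI in metaphocyte-like cells, a ratio of 8386 (counting interval 1505 to 331232), and the complement gene c7b 2 UMIs, a ratio of 629 (counting interval 174 to 5197). The adjusted p was at most 0.006 for each of these genes (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The calls of tyrobp (2.18 ± 0.65) and the adaptor gene myd88 (1.27 ± 0.26) were lost with a mitochondrial maximum of 10%, those of itga3a (1.04 ± 0.26) and ier2b (1.12 ± 0.13) with DESeq2, that of mcm5 (-3.87 ± 0.96) with separate parts of the UMIs and that of the lipase gene lpl, at least 9.76-fold lower, with no filter on low counts.

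Keratinocyte-like and macrophage-like cells gave the reference axis and differed in 4833 genes, 2598 higher and 2235 lower in keratinocyte-like cells. epcam (log2 fold change 7.87 ± 0.31) and cdh1 (6.79 ± 0.25) were higher in keratinocyte-like cells (adjusted p = 2.5e-13 and 1.0e-13 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of the tight junction genes, 26 of 27 measured members rose and 0 fell, and of the adherens and desmosome genes, 31 of 33 measured members rose and 1 fell (camera adjusted p = 2.2e-12 and 2.0e-18). Of the lysosome genes, 0 of 35 measured members rose and 29 fell, of the phagocytosis genes, 0 of 25 measured members rose and 23 fell, and of the MHC class II genes, 0 of 14 measured members rose and 10 fell (camera adjusted p = 2.5e-23, 2.5e-23 and 9.4e-09). With an estimated correlation, these 5 lists had adjusted p = 0.0046, 0.011, 0.0046, 0.0061 and 0.0046. Adjusted over the list alone, their counts were as over all genes, and each list contained genes that had named one of these classes except the lysosome list. Without these genes, 24 and 0 tight junction genes rose and fell, 28 and 1 of the adherens and desmosome list, 0 and 18 of the phagocytosis list and 0 and 5 of the MHC class II list. Among changed genes that passed the count filter, the simulated test recovered 26 of 69 changed 2-fold (37.7%) and 69 of 86 changed 4-fold (80.2%), over 8393 genes. The median log2 fold change of all genes was 0.30 in edgeR and 0.01 with DESeq2's size factors, with a median difference per gene of -0.15. With DESeq2, the split of called genes turned to 2198 higher and 2479 lower, and with a mitochondrial maximum of 10% to 2162 higher and 2374 lower.

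The place of metaphocyte-like cells on that axis was read from genes that separate the 2 reference classes. Genes at least 4-fold apart between keratinocyte-like and macrophage-like cells were chosen in a library and the metaphocyte-like level was then read in the other library. Of 757 genes higher in macrophage-like cells of replicate 1, 44.9% lay above the midpoint of the 2 classes in metaphocyte-like cells of replicate 2, with a median position of 0.433 (0 is the keratinocyte-like level and 1 the macrophage-like level). Of 475 genes higher in keratinocyte-like cells, 29.1% lay above the midpoint, with a median position of 0.175 (0 is the macrophage-like level and 1 the keratinocyte-like level). With the libraries exchanged, the shares were 44.7% of 733 macrophage genes and 29.8% of 483 keratinocyte genes. Over the alternatives the median position of the keratinocyte genes ranged from 0.149 to 0.277, the highest for those chosen in replicate 1 with a minimum of 2000 UMIs, and their share above the midpoint from 28.1% to 31.0%. The 95% exact binomial intervals were 41.3% to 48.5% for the macrophage genes and 25.0% to 33.4% for the keratinocyte genes chosen in replicate 1. They take genes as independent, which genes of a shared programme are not, and no p-value was computed.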

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

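Both tests in this part were chosen after the result had been seen. UMIs of DsRedx, a red fluorescent protein sequence that no comparison used, numbered 113 in replicate 1 and 148 in replicate 2, above the 3 counts that an observed 0 allows, although no label names such a reporter in these fish. Free RNA from the cells of these libraries was argued against: barcodes of at least 1000 UMIs held 0 DsRedx UMIs where the level in empty barcodes gives 7.59. Carry-over of molecules from another library sequenced together stays open and may explain the pattern, since 100% of the DsRedx barcodes with 10 to 300 UMIs also occurred in the other library, against 47.0% of all such barcodes in the library with the higher share. Which library that was is not known from these data, and no biological explanation was tested, since the design has 1 group.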

How the results depend on the processing

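Subtraction with barcodes of 1 library and, for gene lists, the mitochondrial maximum of 10% were chosen after the data had been seen. All counts of called genes stayed within 1.5 times their value under every alternative that gave a count. They were 4294 to 6696, 3108 to 4118 and 3971 to 5411 genes for the 3 comparisons in the order of the report. Without the fold minimum, 7562, 4881 and 5770 genes passed by the adjusted p alone. With the replicate block, 5313, 3807 and 4800 genes were called. Among the named genes and lists, the block ended only the calls of zeb2b and of the pattern recognition list given in the report. The metaphocyte-like share was 11.0045% with a minimum of 500 UMIs, 13.6% with 2000 and 13.1% with a mitochondrial maximum of 10%; the keratinocyte-like share was 48.4%, 56.9% and 46.8% under these, 48.2% with doublet calls kept, 50.4% at resolution 2, 50.4% without list and marker genes and 51.02% with separate parts of the UMIs, and the macrophage-like share was 3.64% with the mitochondrial maximum of 10%. With that maximum, the macrophage-like class held 223 cells, against 184 with the main settings, although a lower maximum only removes barcodes before doublet calling. The class thus took in cells that were outside it before. Calls against macrophage-like cells under that maximum may therefore also reflect a changed class. The cause of these changes was not tested. Without thinning, 85.0% and 74.0% of metaphocyte-like cells had a UMI of spic and il22ra2, because more UMIs per cell were read. With an estimated correlation, 1 list was called against keratinocyte-like and 4 against macrophage-like cells. With each library left out no spread remained for a test. Log2 ratios of TMM-scaled CPM with 1 added, lower by construction, were 6.07 to 6.35 for spic and 7.36 to 7.66 for il22ra2. The levels in CPM printed elsewhere are not TMM-scaled. Of 1274 and 1237 values of named genes, 14 and 20 lost the call, 0 and 7 gained it and none reversed, libraries left out aside. At this depth il22 could not be tested.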

Other observations

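The division of the metaphocyte-like cells, the view of mucous or goblet-like cells with spic and all tests in this part were chosen after the results had been seen. Among the unnamed clusters, cluster 14 carried avil at 607 ± 89.9 CPM and gata2b at 1139 ± 76.7 CPM (SD, n = 2), but under 3 of the fixed markers. Cluster 20 combined basal keratinocyte markers with the retinoic acid synthesis gene aldh1a3 at 5109 ± 1337 CPM, the G protein gene gng13a at 3358 ± 631 CPM and pou2f3 at 509 ± 102 CPM. Cluster 13 carried the costimulatory receptor gene cd28 at 482 ± 70.5 CPM, and cluster 16 the invariant chain gene cd74a at 70908 ± 5567 CPM, il12bb at 1410.2 ± 157 CPM and the dendritic cell receptor gene flt3 at 145 ± 0.875 CPM.

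The metaphocyte-like cells fell into clusters that differed in il22ra2. With clustering and test on separate parts of the UMIs, the cluster of 356 cells with more il22ra2 and that of 496 with less differed in 639 genes higher and 729 lower of 6977 in edgeR's quasi-likelihood test. A clustering can also cut a gradient into such pieces. The calls and list tests here therefore cannot tell separate groups of cells from a gradient. il22ra2 stood at 861 ± 32.3 against 168 ± 18.7 CPM (2.21 ± 0.08), while spic differed by -0.34 ± 0.09. The cluster with more il22ra2 was also higher in ccl35.1 (4.32 ± 0.07), grn1 (3.94 ± 0.05), itgb2 (2.49 ± 0.10), il12bb (2.65 ± 0.07) and the dendritic cell factor gene batf3 (3.22 ± 0.21), and lower in krt4 (-4.36 ± 0.14), myclb (-5.40 ± 0.24), the transcription factor gene her9 (-2.70 ± 0.15) and the taste-cell channel gene trpm5 (-2.59 ± 0.17). The adjusted p was at most 1.8e-10 for each (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). In limma's camera, the lysosome (adjusted p = 7.7e-18), MHC class II presentation (3.8e-09), phagocytosis (1.3e-05), chemokine (3.3e-04), antimicrobial (0.0063) and tight junction lists (0.0063) were higher in the cluster with more il22ra2, and the keratins (0.001) and stress genes (0.018) lower. The adherens and desmosome list was not called (camera adjusted p = 0.21), and with an estimated correlation no list was, the lowest camera adjusted p being 0.21. The IL-22 axis list is not read here, since it holds il22ra2, by which the clusters were ordered. Over the 3 metaphocyte-like clusters of all UMIs, in falling order of il22ra2, epcam stood at 2223 ± 3.87, 2323 ± 54.1 and 2233 ± 88.5 CPM and cldnh at 6388 ± 74.1, 3427 ± 45.2 and 647 ± 80.2 CPM.

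RNA quality, read from the mitochondrial share only, and RNA of other cell types were argued against as explanations of the il22ra2 difference. Depth was compared too. Dissociation stress, whose list was lower in the cluster with more il22ra2 with the preset correlation, was not weighed. The ratio of median UMIs per cell in the cluster with more il22ra2 over that with less was 0.967. CPM is already scaled for UMIs, so that ratio bears little on a difference in CPM. The median mitochondrial share in the cluster with less over that with more was 0.990, so that share did not differ enough. RNA of other cell types would have to make up 80.5% of the cluster with less il22ra2. For the abundant genes of each other named class or unnamed cluster, the rise over the cluster with more il22ra2 was taken. As a share of the gap between that cluster and the class, the median rise per class or cluster was 2.16% at most. No biological explanation was tested, since the design has 1 group.

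In the mucous or goblet-like class, 14 cells (7 in each library) held all 62 spic UMIs of the class. Doublets with, or free RNA of, metaphocyte-like cells were argued against: grn2 stood at 57.5 CPM, 0.0747% of what the spic level would bring with it, or 1.19% by the metaphocyte-like cluster with the least grn2, by which 17.7 il22ra2 UMIs would come with it and 0 were seen. The summed level in these cells, the other cells of the class and metaphocyte-like cells was 1080.5, 106 and 2834 CPM for the chemokine receptor gene cxcr4b, 374, 35.7 and 186 CPM for prox1a and 109, 7.27 and 381 CPM for the myeloid kinase gene hck, with no test. Of the UMIs that the spic level would bring with it by that cluster, cxcr4b reached 26.2%, hck 28.0% and cd83 37.4%. No biological explanation was tested.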
